A study of Mus with 12 samples.

How the data were processed

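The study used F4/80-selected cells from the kidneys of 6 mice, 3 wild type (WT) and 3 lacking Aif1 (KO). Per the labels' protocols, the left kidney was made ischemic for 30 min and both kidneys were harvested at day 4. The tissue was digested to single cells, and cells carrying F4/80 were pulled out with a biotin-labelled antibody and an immunomagnetic selection kit. RNA was isolated with a column kit and processed by the manufacturer's NanoString protocol, per the labels. The name of the probe panel, the amount of RNA loaded, the cartridge and lane of each library, and the counting software are not given in the sources used here.

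The deposited table holds counts, per the file: whole numbers for 768 probes in 12 libraries, whose totals differ between libraries and whose control probes still stand in the table. No normalization by the authors is recorded in the sources used here, and the spread of the totals shows none, so the values were treated as raw counts. Of the 768 probes, 741 were taken as endogenous genes, 13 as housekeeping genes by a list of names fixed beforehand, 6 were positive controls of known concentration and 8 were negative controls with no target. All sample columns were used. Gene symbols were used as the file gives them. Of the 754 gene probes, 744 matched a symbol in an NCBI RefSeq table of the mouse assembly GRCm38.p6, 9 matched by a synonym and 1 did not match. Probe sequences were not given, so no genomic position is reported.

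Samples were grouped by the labels' genotype and by their tag for injury, giving 4 groups of 3. The library names carry a mouse number and the side of the kidney, and the series' design text makes each mouse's contralateral kidney its own control. Both kidneys of a mouse were therefore paired through the mouse. As a check, the deviations of each library from its group mean were correlated across genes. The correlation between the kidneys of a mouse was 0.96 in mouse 12, 0.88 in mouse 26 and 0.72 in mouse 36, all WT. It was 0.37 in mouse 23, -0.12 in mouse 17 and -0.49 in mouse 32, all KO. For mice 17, 32 and 36 a kidney of another mouse correlated more highly (0.54, 0.42 and 0.86). The pairing rests on the shared animal, not on these values. No replicate libraries agreed within sampling noise. The lowest chi-square per degree of freedom between replicates was 5.92, and their Spearman correlations ran from 0.72 to 0.95.

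A gene was kept where its raw count reached 53.1 in at least 3 of the 12 libraries. That threshold is the mean plus 2 SD of the negative controls, and 689 of 741 endogenous genes passed. Counts were scaled with TMM factors over the kept genes. Normalised counts are counts divided by each library's effective size relative to the geometric mean size of 232617. The injury comparisons were fitted with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) over all 12 libraries with mouse as a fixed block. The coefficients gave the response in WT mice, the response in KO mice, their mean and their difference. KO and WT mice were compared in injured and in contralateral kidneys by edgeR on the means of the 4 groups, without a block, and over both kidneys by limma 3.58.1 with a trended prior on each mouse's mean log2 library-scaled counts (edgeR's cpm, prior count 1). P-values were adjusted by the Benjamini-Hochberg method over the 689 genes of each comparison, and genes with an adjusted p under 0.05 were called. Standard errors of edgeR fold changes were taken as the absolute log2 fold change over the square root of its F value.

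The 25 gene lists for pathways and cell types were fixed before the data were examined, as were the tests and the alternatives unless stated otherwise. They cover cytokines, chemokines and their receptors, alternative activation, antigen presentation, interferon, complement, toll-like receptor, inflammasome, phagocytosis, matrix, STAT and cell cycle genes, and markers of macrophages, monocytes, neutrophils, dendritic cells, T cells, B cells, NK cells, mast cells with basophils and eosinophils, endothelium with platelets, and kidney epithelium with stroma. The 23 lists with at least 5 kept members were tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, for change one way and in either direction, with adjustment over the lists of each comparison. The B cell and NK cell lists had too few kept members. The panel is itself rich in immune genes, and camera compares a list with the rest of the panel. Genes named in the text are Aif1, the 12 with the largest positive and the 12 with the largest negative log2 fold change among the genes called in a comparison, up to 4 members per list with the smallest p, and, where fewer than 10 genes were called, the 10 with the smallest unadjusted p. Names outside that rule are said to be so.

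The amount of RNA, read from the housekeeping counts, differed strongly between libraries. Between the 3 libraries with the highest and the 3 with the lowest housekeeping counts, housekeeping counts differed 6.69-fold and negative controls 1.05-fold. The highest were both libraries of WT mouse 12 and the injured library of KO mouse 17. The lowest included the contralateral library of KO mouse 17. Of the 741 endogenous probes, 220 differed by less than 1.5-fold, and 183 of these passed the filter. Such a count, here called flat, falls when it is divided by a larger library and rises when it is divided by a smaller one. The positive controls add up to between 117110 and 142481 counts per library, so hybridisation and counting differed far less than the RNA.

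The 7 comparisons and their list tests were tested on simulated counts, the alternatives and the scaling to macrophage genes were not. Counts were drawn from negative binomial distributions with the real library sizes and dispersions, and 200 genes were changed by 1.5-, 2- or 4-fold. The means were those fitted to each mouse for the injury comparisons, and a common share of the library per gene for KO against WT. For the mean response of both genotypes, over 683 genes, 60.6% of the genes changed 1.5-fold, 93.9% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 5.68% of the calls were unchanged genes. For KO against WT in injured kidneys, over 682 genes, 3.03%, 21.2% and 87.7% were recovered. For the difference of the responses, over 684 genes, 2.99%, 38.8% and 95.4% were recovered. With no gene changed, 1 gene was called for KO against WT in injured kidneys and 0 in each of the other comparisons. A change of 1.5-fold in the 21 macrophage markers was called by camera in all 7 comparisons, and camera also called 1 other list for the mean response and 1 for the difference. Some other lists share genes with the changed list, and which list was called was not recorded. Such a call is therefore not shown to be false. Fry called 2 lists for the KO response and 3 for the mean response, the changed list among them. It missed the changed list for the difference (adjusted p = 0.0967). With an estimated correlation camera missed the changed list for the KO response (adjusted p = 0.0678) and the difference (0.277). The simulated genes were independent of each other and had no background that ignores the amount of RNA. For KO against WT the kidneys of a mouse were also drawn independently, without a shared mouse effect.

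The alternatives were DESeq2 size factors, housekeeping scaling, no filter, a minimum of 50 counts, quantile normalization with limma, DESeq2 1.42.0, no replicate block, mouse as a random block, each genotype or side fitted alone, and leaving out each mouse in turn. For the mouse means, a prior count of 20 and limma without a trended prior were used. Subtraction of the mean negative control, a minimum of 200 counts, scaling by the positive controls, leaving out mice 12 and 17 and leaving flat probes out of the lists were chosen after seeing the data. In the subtraction, counts that did not exceed the mean negative control were set to the smallest positive count. Scaling to 5 macrophage genes and scaling to the whole macrophage list were also tried after seeing the data. Both measure a change relative to macrophage genes, so after their results were seen they were reported as tests of an explanation and not as alternatives. Figures were drawn with matplotlib 3.10.9.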

Results

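Expression of an immune gene panel was counted with NanoString probes, fluorescent barcodes that are counted on single RNA molecules, in kidney cells selected for F4/80, a surface protein of mouse macrophages. The cells came from 3 wild-type (WT) mice and 3 mice lacking Aif1 (KO), the gene of a calcium-binding, actin-associated protein of macrophages also known as Iba1. Each mouse gave an injured left kidney, harvested at day 4 after 30 min of ischemia, and an uninjured contralateral right kidney. The 12 libraries thus formed 4 groups of 3, with the mouse as the replicate (WT mice 12, 26 and 36; KO mice 17, 23 and 32).

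Total counts ran from 255274 to 904220 per library, and the endogenous genes took 109192 to 722084 of them. The geometric mean of the housekeeping genes ran from 180.1 to 1470, an 8.16-fold range, while the positive controls differed 1.22-fold. Housekeeping counts of the injured kidney were 4.64 times those of the contralateral kidney in KO mouse 17 and 2.01 times in KO mouse 23, but 0.77 times in KO mouse 32. In WT mice 12, 26 and 36 the ratios were 1.03, 1.34 and 0.61. Both libraries of WT mouse 12 stood apart, with housekeeping counts of 1430 and 1470 against 198 to 423 in the other WT libraries and a Spearman correlation of 0.72 between its injured library and each of the other 2 injured WT libraries, which correlated at 0.95 with each other. The injured library of KO mouse 17 (1080) also lay above the other KO libraries (180.1 to 500). Klk1 and Egf, both expressed by kidney tubule cells, were the most abundant genes of the panel, with 3.97% and 3.36% of endogenous counts on average. Cd74, the invariant chain of MHC class II, followed with 2.82%, and the early response gene Atf3 with 2.17%. In the contralateral WT libraries, raw Klk1 ran from 3387 to 55136 and Egf from 4270 to 70041, both highest in mouse 12. The macrophage genes Csf1r and Adgre1, chosen after their values were seen, ran there from 387 to 448 and from 312 to 426. In the injured KO libraries Klk1 ran from 1715 to 49240 and Csf1r from 261 to 1731. The source of the additional RNA in mouse 12 was not tested.

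**Figure D1:**
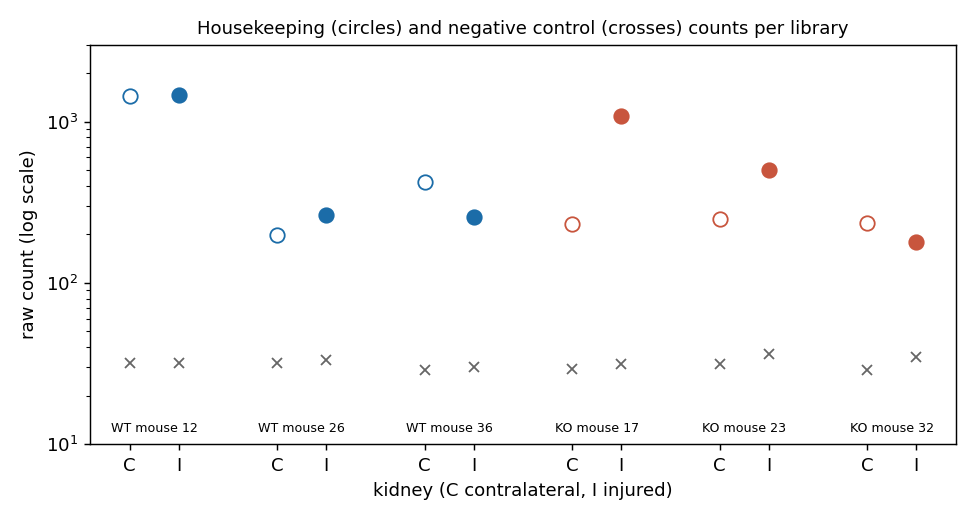
Raw housekeeping counts (geometric mean of 13 genes, circles) and mean negative control counts (crosses) of each library on a log axis, with open circles for contralateral (C) and filled circles for injured (I) kidneys, WT in blue and KO in red. Housekeeping counts span 180.1 to 1470, whereas the negative controls stay between 28.8 and 36.3.

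Aif1 itself did not separate the genotypes. Its raw count was 66.3 ± 8.1 in contralateral and 84.7 ± 10.5 in injured kidneys of WT mice, and 69.3 ± 14.6 and 79.3 ± 14.6 in those of KO mice (SD, n = 3 each). All 12 values lay between 54 and 95, above the threshold of 53.1 and above the mean negative control of 28.8 to 36.3 of each library, while the highest single negative control read 58. The mouse means differed by 0.26 on the log2 scale (KO minus WT), with an exact two-sided permutation p of 0.8, where 0.1 is the smallest p that 3 mice against 3 allow. Without mouse 12 that difference was -0.29. The fitted response to injury was 0.32 in WT and -0.53 in KO mice, although the raw count was higher in the injured kidney of 6 of 6 mice, and the difference of the responses, -0.85, did not pass (edgeR adjusted p = 0.41). The Aif1 count was 1.03 times as high in the 3 libraries with the most RNA as in the 3 with the least, where housekeeping counts differed 6.69-fold. Those with the most RNA were both libraries of WT mouse 12 and the injured library of KO mouse 17. The ratio alone therefore does not show that the probe read background. The probe checked neither the labels nor the deletion, and its target region within the gene is not known here.

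The first comparison asked what ischemic injury changed in the selected cells, with each mouse's contralateral kidney as its control and the responses of both genotypes averaged (6 mice). The monocyte-attracting chemokine gene Ccl2 rose from 259 ± 75.1 to 939 ± 399 normalised counts (SD, n = 6) in the injured kidneys, and the paired fit gave a 3.41-fold difference. The lipid carrier gene Apoe rose 3.38-fold by the fit. Il1rn, the interleukin-1 receptor antagonist, rose by 2.43 ± 0.29 on the log2 scale (SE, n = 6 mice) and Il1a, which encodes interleukin-1 alpha, by 2.04 ± 0.26. Cd84, a receptor of the SLAM family, rose by 1.89. These 3 values are no exact folds, since the raw counts of the contralateral kidneys (16 to 24 for Il1rn, 8 to 24 for Il1a, 19 to 68 for Cd84) lay below or around the mean negative control of 28.8 to 36.3, and subtraction of that background gave 6.26, 4.46 and 3.56. All contralateral counts of Il1rn and Il1a, and the lowest of Cd84, lay below the background and were set to a floor, the smallest positive count. The 6.26 and 4.46 therefore depend on that floor, and the 3.56 does in part. Egf, the growth factor of the distal tubule, fell to a fitted 0.288 times its contralateral level.

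In total 57 of 689 genes were called, 53 higher and 4 lower in the injured kidney (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of the 53, 40 were higher in the injured kidney of all 6 mice. The smallest adjusted p, 8.39e-05, was shared by Ccl7, Ccl9 and Il1rn. The 12 largest fitted increases were those of Il1rn, Il1a, Cd84, Ccl2, Apoe, Ccl9, Ccl7, Cxcl2, Ccl5, Fn1, Cd68 and Itgam, between 2.43 and 1.27 on the log2 scale, an order that background subtraction changed. The 4 genes that fell were Egf (-1.80 ± 0.49, adjusted p = 0.032), the collagenase gene Mmp13 (-0.91 ± 0.17, adjusted p = 0.0019), Fbp1 of gluconeogenesis (-0.85 ± 0.24, adjusted p = 0.040, and -1.71 after background subtraction) and Enpp2, which encodes autotaxin (-0.67 ± 0.18, adjusted p = 0.027), each lower in 6 of 6 mice. Egf was no longer called without mouse 23, 26 or 36 (adjusted p = 0.092, 0.10 and 0.18), nor were Fbp1 and Enpp2 without mouse 12, 23 or 36 (adjusted p from 0.051 to 0.44). The Mmp13 count was flat, hardly moving with the amount of RNA.

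**Figure D2:**
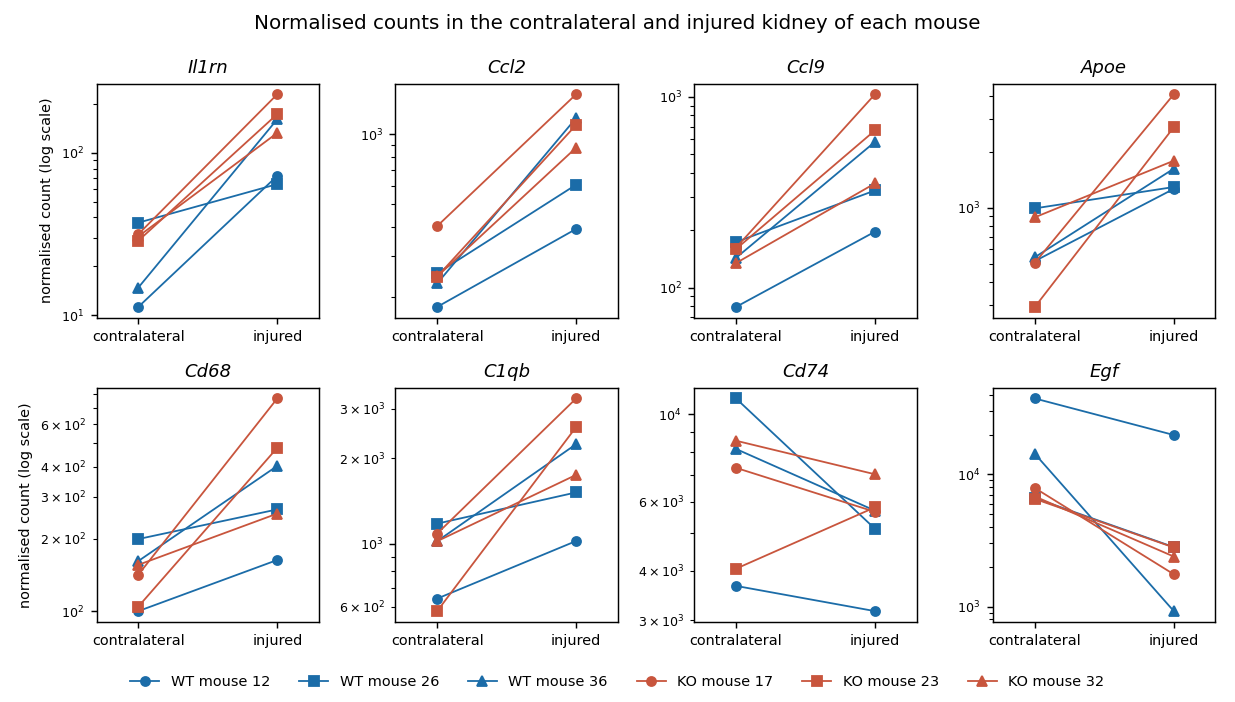
Normalised counts (log axes) of 8 genes in the contralateral and injured kidney of each mouse, with a line per mouse, WT in blue and KO in red. Il1rn, Ccl2, Ccl9, Apoe, Cd68 and C1qb are higher and Egf is lower in the injured kidney of 6 of 6 mice, while Cd74 is higher in 1 of 6.

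Macrophage, complement and phagocytosis lists were called higher at the preset correlation. Of 21 measured macrophage markers, 12 rose, and 13 did when adjusted over the list alone. Among them were the phagocyte markers Cd68 (1.31 ± 0.21) and Itgam (1.27 ± 0.19), the mannose receptor gene Mrc1 (1.26 ± 0.19) and the lipid-sensing receptor gene Trem2 (1.13 ± 0.18). The F4/80 gene itself, Adgre1, named as the selection marker after its values were seen, rose by 0.67 ± 0.18 (adjusted p = 0.032) and was called in 1 of the 6 fits that left out a mouse, that without mouse 32. Of 8 complement genes, 6 rose (7 over the list alone), with Itgam, the anaphylatoxin receptor genes C5ar1 (0.95 ± 0.18) and C3ar1 (0.90 ± 0.19), and C1qc (1.12 ± 0.23), a subunit of C1q. C1qc, C3ar1 and Cx3cr1 were not called without mouse 23 (adjusted p = 0.10, 0.063 and 0.083). Of 21 genes of Fc receptors, scavenger receptors and phagocytosis, 10 rose (12 over the list alone), including the Fc receptor gene Fcgr3 (1.15 ± 0.19). The camera adjusted p was 1.23e-10 for the macrophage, 4.16e-08 for the complement and 1.43e-06 for the phagocytosis list. These lists overlap, and these 3 calls were lost with an estimated correlation (adjusted p = 0.34 each). With fry, which asks whether a list moves one way, the adjusted p was 0.031 for each.

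A minority of the chemokine genes rose. Of 13 C-X-C and other chemokine genes, 4 rose, also over the list alone. They were the neutrophil-attracting Cxcl2 (1.39 ± 0.27) and Cxcl1 (1.24 ± 0.23), the platelet factor Pf4 (0.98 ± 0.23) and the interferon-induced Cxcl10 (0.70 ± 0.21). Camera called this list higher (adjusted p = 0.017, and 0.34 with an estimated correlation), though not without mouse 32. Pf4 was not called without mouse 36 (adjusted p = 0.12), nor Cxcl10 without mouse 12, 23, 26 or 36 (adjusted p from 0.091 to 0.55). Of 19 C-C chemokine genes, 4 rose, also over the list alone: Ccl2 (1.77 ± 0.22), Ccl9 (1.74 ± 0.21), Ccl7 (1.57 ± 0.17) and Ccl5 (1.34 ± 0.21). The contralateral counts of Ccl7 (34 to 72) and Ccl5 (36 to 116) began near the negative controls, and background subtraction gave 2.69 and 2.42, above Ccl2 (1.89) and Ccl9 (1.99). The median of the list was nevertheless -0.09, its mean 0.26, and its camera adjusted p 0.18. Among 20 chemokine receptor genes, 4 rose (5 over the list alone), with Ccr2, the receptor for Ccl2 (0.79 ± 0.15), and Cx3cr1, the fractalkine receptor (0.80 ± 0.16), besides C5ar1 and C3ar1. Its adjusted p was 0.45, with a median of -0.17 and a mean of 0.07.

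A minority of the pro-inflammatory and of the alternative activation genes rose, and camera called neither list. Of 22 pro-inflammatory genes, 6 rose, also over the list alone, among them Il1a, Il1rn, the prostaglandin synthase gene Ptgs2 (1.10 ± 0.19) and Osm, which encodes oncostatin M (0.91 ± 0.19). Il1rn in that list encodes an inhibitor. Osm, at 1.80 after background subtraction, was not called without mouse 12, 23 or 36 (adjusted p from 0.063 to 0.065). Of 21 alternative activation genes, 6 rose, also over the list alone, among them Mrc1, Trem2, the scavenger receptor gene Stab1 (1.23 ± 0.21) and the arginase gene Arg1 (1.04 ± 0.24). The camera adjusted p was 0.18 and 0.11, and 10 and 9 of their probes were flat. The pro-inflammatory list had a median of -0.02 and a mean of 0.27. Fry's test for change in either direction passed for 9 of the 23 lists, the pro-inflammatory (adjusted p = 0.0098), alternative activation (0.038), C-C (0.0068) and C-X-C chemokine, MHC class II (0.0098), complement, phagocytosis, macrophage and kidney lists. Without flat probes camera called 9 lists higher, among them the pro-inflammatory, alternative activation, C-C chemokine, chemokine receptor and monocyte lists. Flat probes left the lists but stayed in the rest of the panel, and mouse 17 took part in defining them. That setting can therefore favour higher calls by itself. Without mouse 17 the pro-inflammatory, alternative activation and C-C chemokine lists were called higher. Arg1 was not called without mouse 36 (adjusted p = 0.12). Of 24 growth factor and matrix genes, Fn1, which encodes fibronectin (1.33 ± 0.22), and Tgfb1 (0.71 ± 0.19) rose and Mmp13 fell, also over the list alone (adjusted p = 0.59). Tgfb1 was not called without mouse 12, 23, 26 or 36 (adjusted p from 0.070 to 0.29). In the kidney epithelial and stromal list of 8 genes, the tubule injury marker Havcr1 rose by 1.01 ± 0.19 and Egf fell, also over the list alone (adjusted p = 0.45).

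Camera did not call the MHC class II list. Of 12 measured members, the protease gene Ctss rose (1.23 ± 0.24), also over the list alone, and the adjusted p of the list was 0.47. H2-Eb1 stood at -0.50 ± 0.26 and did not pass (adjusted p = 0.39). Cd74 stood at -0.33 ± 0.36, H2-Aa at -0.51 ± 0.31 and H2-Ab1 at -0.33 ± 0.27, none past the threshold and each lower in 5 of 6 mice, and these 3 were chosen after their values were seen. Under positive control scaling, which moved the median of all genes by 0.34, Cd74 and H2-Ab1 changed sign. Monocyte markers counted 2 of 8 that rose, Fn1 and Ccr2, also over the list alone (adjusted p = 0.34, median -0.07, mean 0.23). Dendritic cell markers counted 1 of 10, Sirpa (0.84 ± 0.19), and endothelial and platelet markers 1 of 10, Pf4, or 1 and 2 over the list alone (adjusted p = 0.45 and 0.25, with a fry adjusted p of 0.045 for the second). Sirpa was not called without mouse 23, 26 or 36 (adjusted p from 0.058 to 0.11).

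In the other lists at most 1 gene was called. Tlr8 (0.63 ± 0.18) rose among 23 toll-like receptor genes (adjusted p = 0.19), Nlrp3 (0.54 ± 0.16) among 14 inflammasome and cell death genes (0.95), Il4ra (0.51 ± 0.15) among 16 STAT and JAK genes (0.17) and Cxcl10 among 13 interferon-stimulated genes (0.59), and none of these 4 lists kept a gene over the list alone. The inflammasome list had a median of -0.01 and a mean of 0.02. Tlr8, Nlrp3 and Il4ra were each not called without mouse 12, 23, 26 or 36, and Il4ra also without mouse 17 (adjusted p from 0.058 to 0.46). No gene was called among 13 MHC class I genes (adjusted p = 0.54), 6 cell cycle genes (0.21, with 1 gene over the list alone), 8 T cell (0.14), 15 neutrophil (0.16) and 12 mast cell, basophil and eosinophil markers (0.18). Of the probes of the last 3 lists 7, 14 and 9 were flat. Without mouse 32 neutrophil and T cell markers were called lower (adjusted p = 0.0059 and 0.025).

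The number of genes called depended on the mice and on the pairing, while all 57 genes kept their sign wherever they were tested. Called whichever mouse was left out were 26 of the 57. Without KO mouse 32 the count was 224 genes (104 higher, 120 lower), and without mouse 12, 23 or 36 it was 35, 28 or 30. Without the replicate block it was 14, and all 14 were among the 57.

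**Figure D3:**
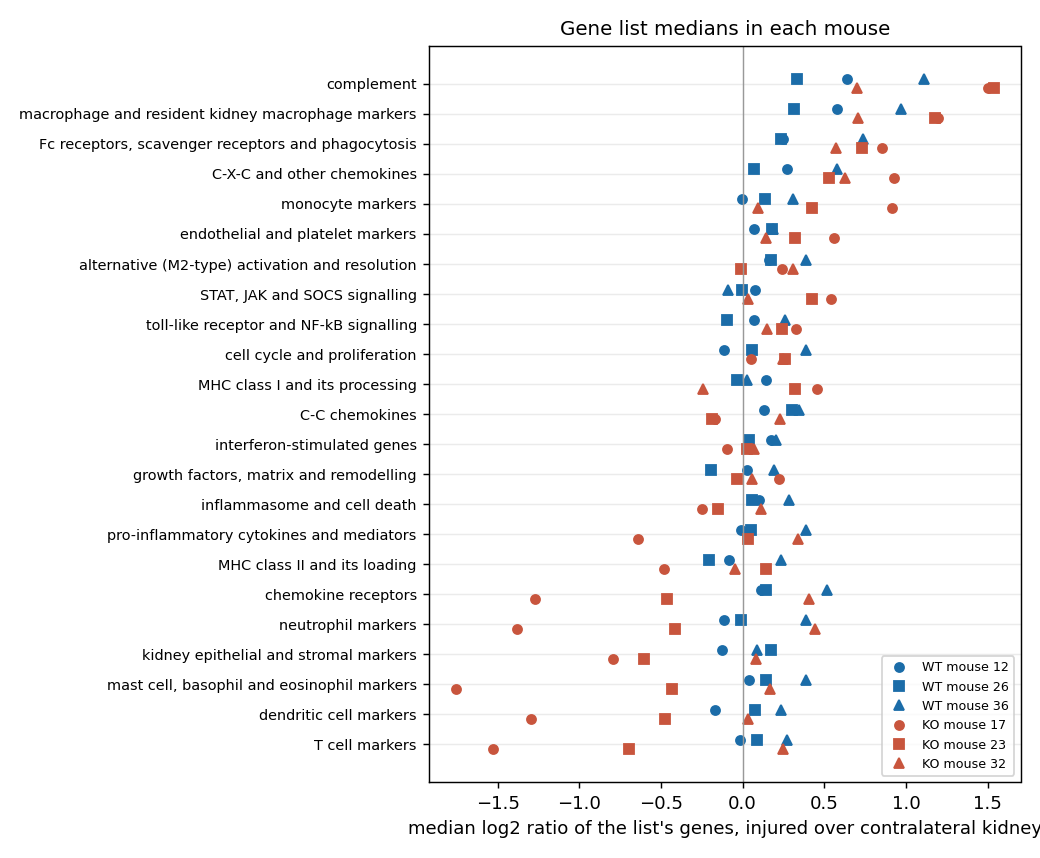
Median log2 ratio of the genes of each of the 23 tested lists, injured over contralateral kidney, with a point per mouse (WT in blue, KO in red). The complement and macrophage medians lie above 0 in all 6 mice (0.31 to 1.54), while the T cell, mast cell and neutrophil medians are lowest in KO mouse 17 (-1.53, -1.75 and -1.38).

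Within each genotype the question was which genes responded to injury in WT and in KO mice. In WT mice edgeR called 5 genes higher and none lower (58 genes had an unadjusted p under 0.05). Lower genes were called by DESeq2 (14 genes, 11 higher and 3 lower) and by a fit on the WT mice alone (55 genes, 35 higher and 20 lower). The 5 genes called higher in the main fit were Il1rn (2.32 ± 0.42, SE, n = 3 mice), Ccl2 (1.58 ± 0.31), Ccl9 (1.42 ± 0.29), Ccl5 (1.32 ± 0.29) and Ccl7 (1.32 ± 0.25), each higher in 3 of 3 mice, with edgeR adjusted p between 0.024 and 0.04999. Background subtraction gave 6.12 for Il1rn, 2.48 for Ccl5, 2.37 for Ccl7, 1.69 for Ccl2 and 1.63 for Ccl9, so neither the order nor the first 3 of these folds is exact. The value of Il1rn depends on the floor that the subtraction set. Mrc1 (1.06 ± 0.26), Ccr2 (0.88 ± 0.22), Itgam (1.02 ± 0.27), Trem2 (0.96 ± 0.25) and Mmp13 (-0.95 ± 0.24) followed without passing (adjusted p from 0.090 to 0.11). The macrophage, complement, phagocytosis, C-C chemokine, chemokine receptor and alternative activation lists were called higher by camera in WT mice (adjusted p from 3.12e-06 to 0.038), and none with an estimated correlation (adjusted p at least 0.48) or one way by fry. In the first 3 of these lists no gene was called over all genes, and 4 of 21, 1 of 8 and 8 of 21 were when adjusted over the list alone. The alternative activation and chemokine receptor calls were lost without mouse 36. The 5 calls became 0 without mouse 12 or 36, 1 without mouse 23 or 26, 27 without mouse 17 (20 higher, 7 lower), 48 without mouse 32 (29 higher, 19 lower), and 0 without the replicate block or with housekeeping scaling. Il1rn was the gene that stayed without mouse 23 and without mouse 26.

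In KO mice edgeR called 47 genes, 46 higher and 1 lower. DESeq2 called 106 (59 higher, 47 lower), and edgeR with DESeq2 size factors called 59 (47 higher, 12 lower). Il1a (2.74 ± 0.38, SE, n = 3 mice), Il1rn (2.53 ± 0.40), Cd84 (2.48 ± 0.39) and Apoe (2.43 ± 0.47) had the largest fitted values, followed by Cxcl2 (2.12 ± 0.39), Ccl9 (2.06 ± 0.29), Ccl2 (1.96 ± 0.31), Fn1 (1.85 ± 0.32), Ccl7 (1.82 ± 0.25), Cd68 (1.80 ± 0.31), Ctss (1.72 ± 0.34) and Cxcl1 (1.64 ± 0.33). Background subtraction gave 6.41 for Il1rn, 5.15 for Il1a, 4.75 for Cd84 and 3.00 for Ccl7, so these 4 are no exact folds and the order is not fixed. The values of Il1rn and Il1a depend on the floor that the subtraction set. Mmp13 fell by 0.87 on the log2 scale and was called without mouse 32 but not without any other mouse (adjusted p from 0.056 to 0.27). Of the macrophage, complement and phagocytosis lists, 11 of 21, 6 of 8 and 9 of 21 genes rose (14, 7 and 12 when adjusted over the list alone, where 1 phagocytosis gene also fell). Camera called these lists and the C-X-C chemokines higher (adjusted p from 7.29e-08 to 0.048) and neutrophil, T cell and mast cell markers lower (0.023, 0.024 and 0.048), none with an estimated correlation (adjusted p at least 0.58) or one way by fry. Without mouse 17 none of the 3 lower lists was called, and without mouse 32 the C-X-C chemokines were not. Housekeeping counts rose with injury in mice 17 and 23, and 14 of 15, 7 of 8 and 9 of 12 probes of the lists called lower were flat. The count was 370 without mouse 32 (167 higher, 203 lower), 14 without mouse 23, where Apoe, Cxcl2 and Ctss were not called (adjusted p = 0.13, 0.089 and 0.16), 3 without the replicate block, 24 with housekeeping scaling and 25 without mice 12 and 17.

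All 5 genes called in WT mice were among the 46 called higher in KO mice, where 0.33 would be shared by independent lists. Both sets came from the same fit with a shared spread for each gene, so they are not independent and 0.33 is too low a baseline. The 53 genes higher on average had positive fold changes in both genotypes, with medians of 0.72 in WT and 1.22 in KO mice. They were picked by the mean of these same responses, so the shared sign is largely set by that choice and supports nothing further. Across the 689 genes, which are not independent replicates, the fold changes of the genotypes correlated with a Pearson r of 0.32 and a Spearman rho of 0.01, and over the 506 genes that were not flat with 0.57 and 0.31. Libraries of both genotypes took part in defining the flat probes, so the last values are not free of that choice.

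Whether loss of Aif1 altered the response to injury was asked by the difference of the responses, KO minus WT. No gene passed (smallest adjusted p = 0.41 by edgeR, 75 genes with an unadjusted p under 0.05, and 0 called by DESeq2). Cxcl2 had the largest positive difference among the 10 genes with the smallest p (1.47 ± 0.53), followed by Man2b1 of the lysosome (1.12 ± 0.33) and Eif4ebp2 of translation control (0.93 ± 0.31). The remaining 7, Lamp3 (-1.51 ± 0.47), Icos, Ifit1bl1, Cdh11, Ido2 (-1.55 ± 0.55), Ccl11 and Fcer1a, had negative differences and flat probes. By camera the macrophage list was higher in KO than in WT mice (adjusted p = 0.024, median 0.47), and neutrophil (0.024, median -0.68), T cell (0.036, median -0.83) and mast cell markers (0.046, median -0.72) were lower. None of these calls held with an estimated correlation (adjusted p = 0.76 for each) and fry called none (adjusted p at least 0.59). Without mouse 32, which leaves the KO mice whose injured libraries held more RNA, 323 genes were called (159 higher, 164 lower). The macrophage median was 0.81 without mouse 32, 0.69 without mouse 36 and 0.32 without mouse 17. The macrophage call was lost without mouse 26 (median 0.37) and the mast cell call without mouse 12 (without mouse 36 the complement and phagocytosis lists were also called higher). Without mouse 17 the 3 lower lists were no longer called and 1 gene was, S100a9 (1.58 ± 0.35), which is named for that reason alone.

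Injured kidneys of KO and WT mice were then compared directly. Fn1 (1.72 ± 0.44), Arg1 (1.89 ± 0.58), Cxcl3 (1.26 ± 0.40), Il1a (1.30 ± 0.44) and Cxcl2 (0.99 ± 0.45) stood higher in KO mice at an unadjusted p under 0.05, but no gene passed after adjustment by edgeR (smallest adjusted p = 0.9997, 3 mice against 3). Fn1 read 558 ± 425 normalised counts in KO and 171 ± 29.9 in WT mice, and Arg1 read 323 ± 244 and 88.4 ± 42.4 (SD, n = 3 each). Apoe (1.04 ± 0.48), Ccl7 (0.95 ± 0.45), Adam8, Cd84 (0.86 ± 0.41) and Rgl1 completed the 10 smallest p, all with higher values in KO mice. Background subtraction gave 3.01 for Cxcl3 and 2.15 for Il1a. DESeq2 called 3 genes higher in KO mice: Arg1 (1.94 ± 0.47, adjusted p = 0.031), Cxcl3 (1.26 ± 0.33, adjusted p = 0.042) and Fn1 (1.70 ± 0.45, adjusted p = 0.042). DESeq2 was not rerun with a mouse left out. The log2 ratio of Arg1, injured over contralateral, was 2.78 in KO mouse 17 and at most 1.12 in the other mice. The macrophage, phagocytosis, complement, C-X-C chemokine and alternative activation lists were higher in KO mice by camera (adjusted p from 3.19e-07 to 0.038), and none with an estimated correlation (adjusted p at least 0.44). Adjusted over the list alone, Fn1 was the 1 gene called in any list (monocyte markers, adjusted p = 0.017). Without WT mouse 12, whose libraries stood apart, none of these 5 lists was called, and without mice 12 and 17 the 3 lists called, chemokine receptors, neutrophil and T cell markers, were lower in KO mice. The C-X-C call was lost without mouse 17 or 26 and the alternative activation call without mouse 17, 23 or 32.

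In the contralateral kidneys no gene separated the genotypes (edgeR, smallest adjusted p = 0.72, 3 genes with an unadjusted p under 0.05, 0 called by DESeq2). Those 3 stood lower in KO mice: Man2b1 (-0.90 ± 0.37), Enpp2 (-1.12 ± 0.49) and the histone gene Hist1h1c (-1.20 ± 0.55). Fbp1 (-1.22 ± 0.57), Lta4h, Tuba4a and Cebpb (-0.74 ± 0.40) were also lower, and Igf2, Batf (0.88 ± 0.44) and Serpinb2 higher, without passing. Igf2 changed sign under positive control scaling, which moved the median of all genes by -0.67. No list was called by camera, though 3 were without mouse 12, 4 without mouse 26, and the C-C chemokines alone without mouse 23, 32 or 36.

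Over both kidneys of each mouse, KO against WT, again no gene passed (limma, smallest adjusted p = 0.96, 3 genes with an unadjusted p under 0.05, 0 called by limma without a trended prior). These 3 were Fn1 (0.91 ± 0.34), Arg1 (1.21 ± 0.46) and Il1rn (0.81 ± 0.34), all with higher values in KO mice. Cxcl3 (0.79 ± 0.37), Serpinb2, Ccl7 (0.76 ± 0.42) and Ccl2 (0.59 ± 0.34) followed in that direction, and Angpt2 (-0.83 ± 0.37), Enpp2 and Hist1h1c stood lower. Camera called the phagocytosis, complement, macrophage, C-C chemokine, alternative activation and pro-inflammatory lists higher in KO mice (adjusted p from 0.0031 to 0.025), none with an estimated correlation (adjusted p = 0.78 for each). No list was called without KO mouse 17, and without WT mouse 12 none of these 6 was. Without mice 12 and 17 the macrophage list was called lower in KO mice. The pro-inflammatory call was also lost without mouse 32 or 36.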

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

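The tests of explanations in this part were chosen after the results were seen, except the counts over other assignments and splits, which were set beforehand. Of 68 values of the paired log2 ratios (genes, lists and housekeeping counts), 2 had a mouse far from the other 5, where chance gives about 3.4. The log2 ratio of Osm was 0.44 in mouse 26 and at least 0.87 in the others. That of Arg1 was 2.78 in mouse 17 and at most 1.12 in the others.

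Camera's test of the difference of the responses called 4 gene lists at a preset correlation: macrophage markers were higher in KO mice (adjusted p = 0.0238), and neutrophil (0.0238), T cell (0.0359) and mast cell, basophil and eosinophil markers (0.0459) were lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.763 each), while fry called none (adjusted p at least 0.59). For the 3 lower lists, background that does not move with RNA is a candidate explanation. The median raw count of their 35 genes was 1.21 times as high in the injured as in the contralateral kidney of mouse 17 and 1.10 times in mouse 23, where housekeeping counts were 4.64 and 2.01 times as high, and none of the 3 lists was called after background subtraction. The raw ratio restates the lower normalised values, given the larger library, so it is no separate support. It cannot tell probe background from a real fall relative to the rest of the RNA. The test by raw counts and background subtraction replaced an earlier one on mouse 17 alone. Without that mouse none of the 3 was called, but the T cell list was still called with mice 12 and 17 both left out. For the macrophage list, more RNA in the injured library of mouse 17 cannot be told apart from an effect of genotype. Without that mouse the list was still called by camera at the preset correlation (adjusted p = 0.0087), and its median difference was 0.32 against 0.47 with all mice (median SE of a gene 0.38 and 0.39). With an estimated correlation camera called it neither with all mice (0.763) nor without mouse 17 (0.862), so that setting says nothing about this mouse. Without WT mouse 26 the list was not called at the preset correlation (0.12, median 0.37). For the difference of the responses, all 10 splits of the 6 mice gave the real count of 0 genes, with 0 as the highest of the others. Every split reaches a real count of 0 whatever the data, so this count tests nothing.

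Aif1 counts did not differ detectably between KO and WT mice. A probe that reads background is a candidate explanation, although all 12 counts lay above the threshold of 53.1: its count rose 1.03-fold between the libraries with the least and the most RNA, where at least 1.5-fold was set as the mark of a probe that measures RNA. The libraries with the most RNA were both of WT mouse 12 and the injured one of KO mouse 17. In contralateral WT kidneys raw Csf1r ran only from 387 to 448, mouse 12 included, and a KO library may hold no Aif1 RNA. A working Aif1 probe could therefore also miss that mark, so the ratio does not decide. Swapped genotype labels cannot be told apart from a background probe, because the exact permutation p of 0.8 comes from the same probe. No biological explanation was tested.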

How the results depend on the processing

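Positive control scaling, background subtraction, the minimum of 200 counts, leaving out mice 12 and 17 and leaving out flat probes were chosen after seeing the data. The 5 WT, 47 KO and 57 average calls kept their sign under every alternative that tested them, and 0, 14 and 26 of them were called whichever mouse was left out. Called on average wherever they were tested were 9 genes: Ccl2, Ccl5, Ccl7, Ccl9, Cd68, Cd84, Il1a, Il1rn and Itgam. Where a cause is not evident from fewer samples or fewer genes, the cause was not tested. Leaving out each mouse gave 0 to 48 genes in WT mice, 14 to 370 in KO mice, 28 to 224 on average and 0 to 323 for the difference, and 0 for KO against WT in each of the 3 comparisons. Lists called then ranged from 4 to 8, 5 to 7, 4 to 7 and 1 to 6 in that order, from 1 to 7 in injured kidneys, 0 to 4 in contralateral kidneys and 0 to 8 over both. Without the replicate block, 0 genes were called in WT mice, 3 in KO mice and 14 on average, and 1 list for the difference; lists were then 4 in WT mice, 5 in KO mice (4 higher, 1 lower, against 4 and 3) and 4 on average, and genes with an unadjusted p under 0.05 went from 58 to 12 in WT mice, 184 to 59 in KO mice, 103 to 62 on average and 75 to 2 for the difference. Housekeeping scaling gave 0 in WT and 24 in KO mice, DESeq2 gave 14 (11 higher, 3 lower), 106 (59 higher, 47 lower) and 3 for KO against WT in injured kidneys, quantile normalization gave 2 in WT mice, and a fit on the genotype alone gave 55 (35 higher, 20 lower) and 27. With an estimated correlation 0 lists were called in each comparison.

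Positive control scaling gave 2 genes in WT mice (1 shared) and 1 for the difference (Il1a, 2.21 ± 0.51). It gave 33 in KO mice and 40 on average, all higher, which shared only 14 of the 47 and 23 of the 57 calls, so that all 4 lower average calls were lost. A minimum of 200 counts gave 28 in KO mice, and leaving out mice 12 and 17 gave 25. Background subtraction left 3 lists in KO mice and 1 for the difference. Without flat probes 11 lists were called in KO mice, 9 on average and 9 in injured kidneys, and for the difference 6, all higher in KO mice, where 1 higher and 3 lower were called with these probes (1 shared). Flat probes left the lists but stayed in the rest of the panel that camera compares against. Both libraries of KO mouse 17 took part in defining them. Leaving them out can therefore favour higher calls in KO mice by itself, so these counts decide nothing. The 3 lower lists (neutrophil, T cell and mast cell markers) then kept fewer than 5 members and were not tested, so their loss is no result. Without mice 12 and 17 they were 7 on average, all higher with injury. For KO against WT they were then 3 in injured kidneys, all lower in KO mice against 5 higher with all mice (0 shared), 3 in contralateral kidneys (1 higher, 2 lower) and 5 over both (1 higher, 4 lower, against 6 higher). Scaling moved the median log2 fold change of all genes: housekeeping scaling by 0.12 in WT mice, -0.23 in KO mice and -0.35 for the difference, positive control scaling by 0.64 in KO mice, 0.34 on average and 0.62 for the difference, and both by more than 0.2 in size in contralateral kidneys and over both kidneys (0.28 and -0.67, 0.24 and -0.29), where DESeq2 size factors moved it by -0.16 and -0.12.

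Reversed signs were those of 4 genes, none of them called. For Aif1, positive control scaling gave 0.12 in KO mice, 0.24 on average and -0.0312 over both kidneys, quantile normalization gave 0.0349 on average, and leaving out mice 12 and 17 gave 0.18 on average and -0.0663 over both kidneys. Leaving out a mouse gave Aif1 a range of -0.356 to 0.0959 on average, -0.620 to 0.190 for KO against WT in injured kidneys and -0.288 to 0.477 over both kidneys. Positive control scaling gave 0.0176 for Cd74, 0.0227 for H2-Ab1 and -0.0806 for Igf2 in contralateral kidneys. Of the single-gene values, 194 lost their call under an alternative, 37 gained one and 1753 stayed. The pseudocount of 20 applied only to the mouse means, since counts were fitted elsewhere. Of the 689 genes tested, 183 had flat probes.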

Other observations

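The ratios in this paragraph were chosen after the data were seen. The 4 MHC class II genes Cd74, H2-Aa, H2-Ab1 and H2-Eb1, divided by Adgre1, Csf1r, C1qa, C1qb and C1qc, fell by 1.28 ± 0.40 on the log2 scale (SD, n = 6 mice), lower in 6 of 6 mice. By themselves the 4 genes stood at -0.42 ± 0.51, lower in 5 of 6 mice, and the 5 macrophage genes at 0.86 ± 0.52, higher in 6 of 6. The 4 genes were picked from the MHC class II list, which camera did not call, so the ratio decides nothing about its source.

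Values of tubule and early response genes were also chosen after the data were seen. Egf was lower in the injured kidney of 6 of 6 mice (-1.83 ± 1.12, SD, n = 6), while Klk1, the most abundant gene, was higher in 2 and lower in 4 (-0.36 ± 1.24), and Atf3, Dusp1, Fosb and Jun together were higher in 3 and lower in 3 (-0.09 ± 0.80). Klk1 and these early genes were highest in mouse 17 (1.40 and 1.22), whose injured library held 4.64 times the housekeeping counts of its contralateral library.

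The tests of explanations for the injury result were chosen after the result was seen, except the count over other assignments. In mice 32 and 36, where the injured library held less RNA, the medians of the 53 genes that rose were 0.77 and 1.14. Both mice also took part in the fit that picked these genes. The medians therefore cannot decide whether more RNA in the injured library explains the rise. A larger share of macrophage RNA in the injured preparations is a candidate explanation that cannot be told apart from a response within the cells: relative to the 5 macrophage genes the median of the 53 was 0.10 (median SE 0.21, lower quartile -0.15), but 4 of these 5 genes are themselves among the 53. After that scaling 8 genes were still called by edgeR (17, these 8 among them, after scaling to the whole macrophage list, which was also tried), but the 8 are those with the largest fold changes of the 53, so they exclude nothing. The other 45 had a median of 0.91 (median SE 0.19) before that scaling and 0.04 (median SE 0.21) after it, so their calls ended because the fold shrank.

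Other assignments of injured and contralateral to the kidneys were counted as a test of chance. On average over both genotypes, 1 of 32 assignments, the real one, gave as many as 57 genes, and the highest of the others gave 27, with the sides of WT mouse 26 exchanged. That share lies under 0.05 but is the smallest that 32 assignments allow, so chance assignment is less likely but not excluded. In WT mice there are 4 assignments and in KO mice 4, too few for a share under 0.05: the real counts were 5 and 47 and the highest of the others 0 and 0. For KO against WT in injured kidneys, in contralateral kidneys and over both, there are 10 splits each, again too few, and the real count and the highest of the others were 0. Every split reaches a real count of 0 whatever the data, so these counts test nothing.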
